A study of Mus musculus with 2 samples.

How the data were processed

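Liver RNA of male C57BL/6J mice fed ad libitum or calorie-restricted was measured on Affymetrix mouse arrays with 45101 probe sets. Per the labels' protocols, total RNA was extracted with Trizol, RNA of 3 mice of a group was pooled in equal amounts, and biotin-labelled cRNA was made from 6 ug of total RNA. The deposited table held 1 column of intensity values per pool, made by the authors with RMA per the submitters' processing notes. RMA is a method that corrects background, normalizes between arrays and summarises the probes of a probe set. RMA commonly returns log2 values, whereas the deposited intensities had medians of 7.35 in AL and 7.42 in CR and reached 14045 in CR, which is a linear scale. The RMA version, the software, the background options and any later scaling were not given in the sources used here. Because RMA normalizes arrays to each other, a shift shared by most genes cannot be seen in these values. The table gave no detection calls, so low values are not separated from background.

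Intensities were transformed to log2 and the difference CR minus AL was taken. The column of each pool was matched to its group through the labels, and no column of another sample was present. Gene names came from the platform's annotation of August 2016. Of the probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none, besides 64 control probe sets. Of 34958 annotation rows with 1 symbol, 34754 matched the GRCm38.p6 gene table by Entrez ID, and no symbol differed from it. No gene was named from a probe set with several symbols. The genome build of the array design was not given in the sources used here, so no coordinates are printed.

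Each gene was represented by its probe set of highest mean log2 intensity. A gene was measured if the higher of its 2 values reached the median of all values over both arrays, an intensity of 7.38 (log2 2.88). Of 18193 genes, 12644 passed and 5549 did not. A gene below that limit in 1 pool is given as "at least N-fold" against the limit. Genes with at least a 2-fold difference were counted, as a rule of size and not as a test. Probe sets of one gene gave a rough view of technical agreement. Among 4924 genes with 2 or more probe sets in the measured range, the median SD of their differences was 0.288, and 52.7% had probe sets of both signs. Depth does not apply to arrays, and the number of arrays, 1 per group, limits the precision.

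Lists of pathway genes and cell type markers, 42 in all, and the rules for naming genes were written before the data were examined. A list's median difference was placed among the medians of 10000 random lists of the same size, drawn from measured genes with the same spread over 10 classes of mean expression. Medians beyond the central 95% were counted. The text names the 15 genes of largest positive and the 15 of largest negative difference whose probe sets in the measured range all had 1 sign. In each list it draws on the 4 members of largest absolute difference and all members of at least 2-fold. Control probe sets for beta-actin, Gapdh and the spikes are named as signs of quality. Some genes of the lists had no probe set with a single symbol in the annotation and were not used here.

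Alternatives written before the data were examined were the mean over all probe sets of a gene, leaving out probe sets of the types that can match several transcripts (_x_at, _s_at and _a_at), no intensity limit, a stricter limit at the 75th percentile (intensity 21.0), centring each array on its median, removing a loess trend on mean expression (span 0.4), a 1.5-fold threshold, and random lists not matched on expression. Chosen after seeing the data were a shift by the median difference of the hybridisation controls, of all or of cre alone, the restriction to genes whose probe sets had 1 sign, and lists without shared members. Leaving out a replicate and permuting groups were not possible with 1 array per group.

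The steps were tested on simulated data before use. For the comparison of CR with AL, simulated over 12708 genes with an assumed noise SD of 0.3, 100% of 50 genes with a planted log2 difference of 2 passed 2-fold, as did 100% of 50 with -2, 98% of 50 with 1.5 and 90% of 50 with -1.5. The planted genes were drawn only from genes with a mean log2 intensity at least 2 above the limit. Of the unchanged genes, 21 passed. Of 200 unchanged lists of 30 genes, 3.00% fell outside the central 95%, and a planted shift of 0.2 was found in 77.5% of 200 lists. These lists were random draws of genes with independent noise, as the random lists were. The shares thus check the calculation and do not cover real lists whose genes vary together. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.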

Results

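Liver gene expression was measured in male C57BL/6J mice, an inbred laboratory strain, that were fed ad libitum (AL) or calorie-restricted (CR) for 12 weeks from 8 weeks of age. CR mice were restricted by 20% in the first week and by 40% in the 11 weeks that followed. Liver RNA of 3 mice per diet was pooled before labelling, and each pool was run on 1 Affymetrix array of 45101 probe sets. The comparison asks which liver genes differed in expression between the 2 diets. With 1 pool and 1 array per diet there was no replicate, no p-value and no estimate of the spread between mice, and the number of arrays limits the precision of every value. Each difference is the log2 intensity of the CR pool minus that of the AL pool and compares these pools. Median intensity over all probe sets was 7.35 in AL and 7.42 in CR, and the upper quartiles were 21.2 and 20.7. Of 18193 genes, 12644 were measured, that is, reached an intensity of 7.38 on at least 1 array.

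The largest differences included genes of fuel use, sex-biased metabolism and the acute phase response. Pdk4, the kinase that shuts pyruvate dehydrogenase and spares glucose, had the largest positive difference, 6.58, with an intensity of 8.10 in AL and 774 in CR. Cyp2b9, a cytochrome P450 more abundant in female liver, followed at 5.97, and the peroxisomal acyl-CoA thioesterase gene Acot3 at 4.41. Serpina4-ps1, a male-biased pseudogene transcript, had the largest negative difference, -6.49, with 1109.9 in AL and 12.4 in CR. Hsd3b5, a male-specific steroid dehydrogenase, had an intensity of 419 in AL and lay below the measured range in CR, at least 56.8-fold lower. The male-biased P450 Cyp4a12a stood at -5.54, the neutrophil chemokine Cxcl1 at -4.28 (another probe set -2.25) and serum amyloid A1, Saa1, at -3.82. In all, 227 genes (1.80% of those measured) were at least 2-fold higher in CR and 353 (2.79%) at least 2-fold lower, against 110 and 230 when all probe sets of a gene were averaged. The median difference over measured genes was -0.02, the central 95% ran from -1.04 to 0.89, and the log2 values of the 2 arrays correlated across genes at r = 0.970, with genes not independent replicates. Of the 2-fold genes, 319 rested on 1 probe set in the measured range, 182 had several with one direction and 79 had probe sets in both directions. Scaling the arrays on the hybridisation control spikes, chosen after seeing the data, moved the median gene to -1.04 and the counts to 33 higher and 6857 lower. The spikes differed by transcript, from 1.13 for bioB to 0.37 for cre, and less for brighter spikes. In AL, bioB intensities began at 75.6 and cre intensities at 5565, against an upper quartile of 21.2 over all probe sets. Scaling on cre alone, the brightest spike and the smallest of 4 differences, gave 96 and 1030. Most probe sets were far dimmer than cre, so its shift may not hold for them. All differences here are relative to the typical gene.

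**Figure D1:**
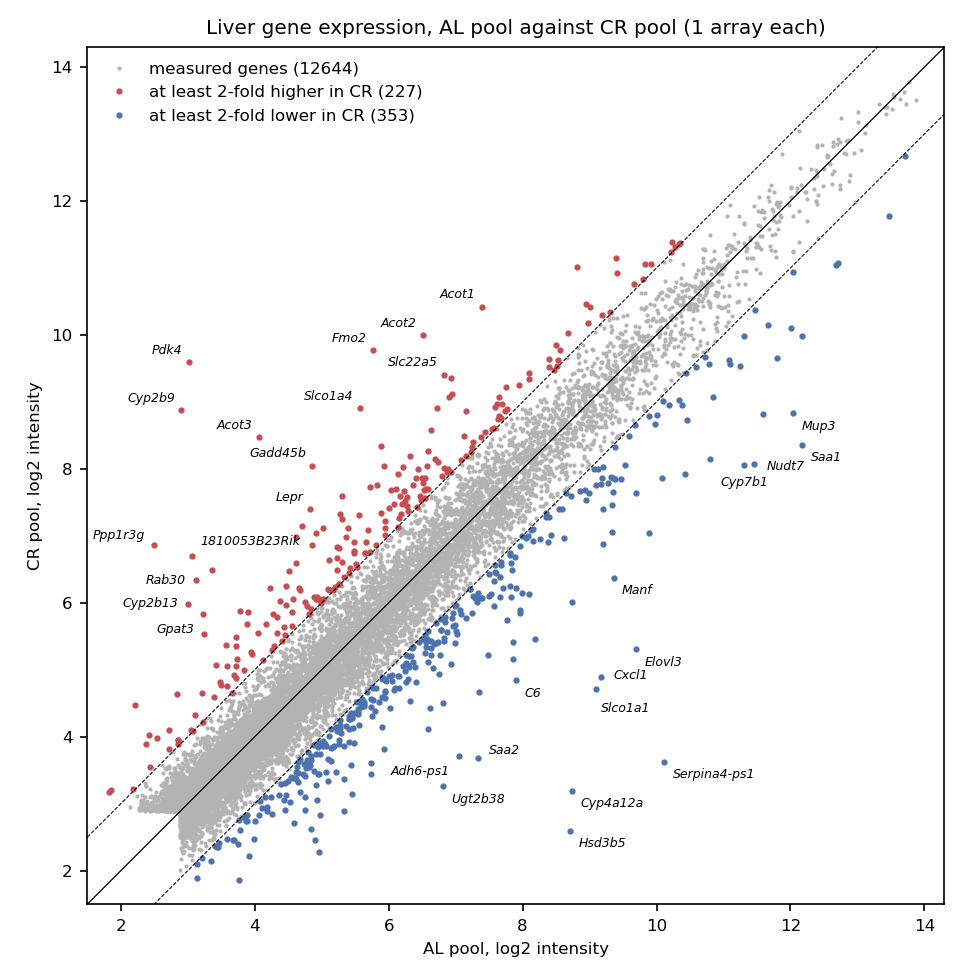
Log2 intensity of 12644 measured genes in the AL pool (x axis) and the CR pool (y axis), 1 array each; each point is a gene, the solid line marks equal values and the dashed lines mark a 2-fold difference. Pdk4 and Cyp2b9 lie farthest above the line of equality (6.58 and 5.97), and Serpina4-ps1 lies farthest below it (-6.49), in values as deposited, while Hsd3b5 is drawn at its CR value below the measured range and was at least 56.8-fold lower.

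The 15 largest differences in each direction were taken among genes whose measured probe sets all had 1 sign. Others of the 15 positive ones were the flavin monooxygenase Fmo2 at 4.01 (lowest probe set 1.63), the organic anion transporter Slco1a4 at 3.34, the Golgi GTPase Rab30 at 3.22 (other probe set 1.88) and the stress-response gene Gadd45b at 3.19 (lowest 1.03). The leptin receptor Lepr stood at 2.57, with 168 in CR against 28.3 in AL, although its other probe set stood at 0.37. Gpat3, an acyltransferase of triglyceride synthesis, stood at 2.61. Ppp1r3g, a glycogen-targeting subunit of protein phosphatase, lay below the measured range in AL and at 116 in CR, at least 15.7-fold higher. Among the largest negative differences were the fatty acid elongase Elovl3 at -4.38, the anion transporter Slco1a1 at -4.39 and the oxysterol hydroxylase Cyp7b1 at -3.25. The glucuronosyltransferase gene Ugt2b38 stood at -3.56, with 113 in AL and 9.58 in CR. Nudt7, a peroxisomal coenzyme A diphosphatase, stood at -3.38, and its 4 probe sets ranged from -3.38 to -0.45. Lists of 42 pathways and cell types, fixed before the data were examined, held 11 of these 15 positive and 14 of these 15 negative genes. The share of all measured genes on the lists was not computed here.

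Genes that male mouse liver expresses more than female liver were lower in the CR pool, and genes that female liver expresses more were higher. Of 32 measured male-predominant genes, 22 were at least 2-fold lower and 1, Ppp1r3g, was higher, with a median of -1.74 that none of 10000 random lists, matched on expression, reached. They included the major urinary protein gene Mup3 at -3.22, the terminal complement genes C6 at -3.06 and C8a at -2.64, and the lung-and-liver P450 Cyp2f2 at -1.77. Of 26 measured female-predominant genes, 12 were at least 2-fold higher and 1, the lipoprotein lipase gene Lpl, was lower at -1.10. A gene below the intensity limit in AL was measured only if it reached the limit in CR, which favours rises among the 26. Their median was 0.93, above all 10000 random lists, and after scaling it was -0.09 on all hybridisation controls, 0.30 on bioD and 0.56 on cre. With no intensity limit the median was 0.78 over the 33 genes with a probe set, again above all random lists. Besides Cyp2b9, Fmo2, Acot3 and Slco1a4, Cyp2b13 stood at 2.97 (8.04 in AL, near the limit), the VLDL receptor Vldlr at 2.09 (other probe set 0.07) and the fatty acid transporter Cd36 at 1.02. Probe sets for close family members, such as Cyp2b9 with Cyp2b13, the Mup genes and the Ugt2b genes, may pick up each other's transcripts, so single members are uncertain. The 5 measured sex chromosome genes had a median of 0.21 and none reached 2-fold. Among them, the Y-linked Eif2s3y, singled out after its value was seen, had intensities of 105 in AL and 103 in CR, and Xist, the X-inactivation RNA, 6.81 and 7.95, close to the lower limit of the measured range.

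Genes of the growth hormone and IGF axis lay in both directions. The cytokine signalling inhibitors Socs2 and Cish, both targets of growth hormone through STAT5, stood at -1.84 and -1.32, and the EGF receptor Egfr at -1.72. The 4 Socs2 probe sets ran from -1.84 to -0.03 and the 5 of Egfr from -1.72 to -0.26. The insulin receptor substrate Irs2 stood at 2.02 and the IGF-binding protein gene Igfbp1 at 1.09. The list's median was 0.02 over 20 measured genes, at percentile 66.0 of random lists, with 10 members above 0 and 10 below. It changed sign, to -0.19 at percentile 5.70, when probe sets of a gene were averaged. Without probe sets that can match several transcripts it was 0.06, at percentile 80.8. Among 27 sirtuin, mTOR and other longevity-related regulators, the NAD salvage enzyme gene Nampt stood at 1.75 and the transcription factor gene Foxo1 at 1.31 (lowest probe set 0.48), with a list median of 0.03 and no member 2-fold lower.

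Several PPAR alpha target genes, which act in fatty acid use, were higher in the CR pool. Of 33 measured PPAR alpha targets and fatty acid oxidation genes, 11 were at least 2-fold higher and none 2-fold lower, and 30 lay above 0. The median was 0.48, above all 10000 random lists, and after scaling it was -0.54 on all hybridisation controls and 0.10 on cre alone. Besides Pdk4, the acyl-CoA thioesterase genes Acot2 and Acot1 stood at 3.48 (other probe set 0.94) and 3.03, the carnitine transporter Slc22a5 at 2.57 and the peroxisome proliferation gene Pex11a at 1.52. The receptor gene Ppara itself stood at 1.04. The other 22 members lay within 2-fold, from Fabp2 at -0.40 to Vnn1 at 0.92. Acot1, Acot2 and Acot3 are close paralogs, so their separate values are uncertain. Without the members it shares with the female-predominant list the PPAR alpha list kept a median of 0.48 over 31 genes, and the female-predominant list without the shared members one of 0.93 over 24 genes.

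The clock and fasting lists were also placed high, with members in both directions. Of 20 measured clock and clock-output genes, 4 were at least 2-fold higher, the deubiquitinase Usp2 at 2.43, the clock repressor Cry1 at 2.05 and the PAR-domain transcription factors Hlf and Tef at 1.94 and 1.34, with other probe sets down to 0.59 and 0.17. In all, 14 clock list members lay above 0 and 6 below, among them the clock genes Npas2 at -0.41 and Arntl at -0.27. The clock list's median was 0.44, at percentile 99.99, and after scaling it was -0.57 on all hybridisation controls and 0.07 on cre alone. The hours of feeding and of liver collection were not given in the sources used here. Of 24 glucocorticoid and fasting genes, Gadd45b, Igfbp1 and the lipoprotein lipase inhibitor Angptl4 were higher, at 3.19, 1.09 and 1.02, and the metal-binding metallothioneins Mt2 and Mt1 lower, at -2.78 and -1.64 (other Mt1 probe set -0.94). That list had a median of 0.27, at percentile 99.43, and after scaling -0.74 on all hybridisation controls and -0.10 on cre alone.

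Carbohydrate, lipid and sterol lists mostly lay within the random range. Gluconeogenesis genes had a median of 0.15 over 17 genes, with Foxo1 alone past 2-fold at 1.31 (lowest probe set 0.48). Pck1 and Ppargc1a stood at -0.01 and 0.42 on their brightest probe sets, but dimmer ones reached 1.36 and 1.45. No probe set of the list in the measured range was 2-fold lower. Of 19 glycolysis and glycogen genes, 1, Ppp1r3g, was at least 2-fold higher and 4 were at least 2-fold lower, among them the glycolytic activator gene Pfkfb3 at -1.87 (other probe set -0.21), the liver glycogen phosphorylase Pygl at -1.20 and the glycogen-targeting subunit gene Ppp1r3c at -1.13. That list's median was -0.20, at percentile 7.09. Fatty acid and triglyceride synthesis genes had a median of -0.14 over 29 genes, with the lipolysis inhibitor G0s2 at 2.20 and the acetyl-CoA carboxylase gene Acacb at 1.06 (other probe set 0.56). In that list 12 members lay above 0 and 17 below, none of them 2-fold lower. The largest negative difference was that of Acly, at -0.84, with probe sets from -1.18 to 0.04. Of 20 cholesterol genes, 3 enzymes of sterol synthesis were at least 2-fold lower, Fdps at -1.64, Sqle at -1.22 and Msmo1 at -1.13, and the list median was -0.09. Each of the 3 rested on 1 probe set of modest intensity, the dimmest Fdps with 30.3 in AL and 9.73 in CR. Of the cholesterol list, 8 members lay above 0 and 11 below. Lipoprotein and hepatokine genes, 2 of them at least 2-fold higher and 2 lower, had a median of -0.20 over 29 genes, at percentile 2.74, with the cholesterol exporter Abca1 at -1.47, and left the random range, at 2.19 and 1.76, after loess and among unmatched random lists. The endothelial lipase gene Lipg stood at 3.12 on its brightest probe set, and its other probe sets reached down to -0.04.

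The bile acid synthesis and transport list was placed low, with 17 members below 0 and 10 above. Of 27 measured genes, 6 were at least 2-fold lower and none higher, among them the steroid dehydrogenase Hsd3b7 at -2.45, the peroxisomal side-chain oxidase Acox2 at -1.48 and the bile salt export pump Abcb11 at -1.42. The list's median of -0.26 lay at percentile 1.12. The median was -0.16 and lay inside the random range, at percentile 12.4, when probe sets of a gene were averaged, and the list lay at 3.85 without probe sets that can match several transcripts. Leaving out its sex-biased members gave a median of -0.26 over 24 genes.

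Chaperones and folding enzymes of the endoplasmic reticulum (ER) were lower in the CR pool. Of 32 measured ER chaperone and unfolded protein response genes, 16 were at least 2-fold lower and none higher, with a median of -0.99 that none of 10000 random lists reached. In all, 27 lay below 0 and 5 above. The 5 were Atf4 at 0.01, Ppp1r15a at 0.19, Eif2ak3 at 0.22, Atf6 at 0.61 (lowest probe set -0.07) and Atf3 at 0.68. The ER stress-induced secreted factor Manf stood at -2.99, the folding factor Creld2 at -2.32, the disulfide isomerase Pdia6 at -2.28 and the ER chaperone Hspa5, or BiP, at -2.19. The calcium-binding chaperone Calr stood at -2.15, and the transcription factor gene Xbp1 at -1.45, with 2163 in AL and 791 in CR. In 14 of the 16 lower genes every probe set in the measured range was lower. Many of the 14, among them Manf, Creld2 and Pdia6, had only 1 such probe set, so no disagreement was possible. Those with several, all lower, were Hspa5, Hsp90b1, Calr, Hyou1, Xbp1 and Syvn1. Pdia3 and Edem1, outside the 14, each had another probe set near 0, at 0.13 and 0.16. Single probe sets of Hspa5, Hyou1 and Xbp1 were also under 2-fold, at -0.30, -0.39 and -0.41. Proteasome subunit genes were lower by less, with 24 of 27 below 0, 1 at least 2-fold lower, Psmb7 at -1.06, and a median of -0.48 that no random list reached, or -0.75 without probe sets that can match several transcripts.

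Other protein quality lists lay within the random range. Cytosolic heat shock genes had a median of -0.19 over 27 genes, at percentile 4.04, with the inducible HSP70 genes Hspa1a and Hspa1b higher at 1.27 and 1.04 (lowest Hspa1b probe set 0.72) and the co-chaperone Stip1 lower at -1.07. Autophagy and lysosome genes had a median of -0.16 over 28 genes, with the mitophagy receptor Bnip3 at 1.16, and lay at percentile 2.35 with no intensity limit. Cytosolic ribosomal protein genes had a median of 0.08 over 28 genes and none past 2-fold. Beside these groups, all 3 beta-actin and all 3 Gapdh control probe sets, which sample the 3', middle and 5' parts of each transcript, were lower in CR, from -0.67 to -1.61. The beta-actin 3' to 5' ratio was 83.5 in AL and 89.7 in CR, and the 3' to middle ratio 11.1 and 20.4. For Gapdh the 3' to 5' ratio was 46.9 and 53.2 and the 3' to middle ratio 4.46 and 6.04. On both arrays the 3' signal far exceeded the 5' signal for both genes, a strong 3' bias. Whether it came from RNA quality or from labelling was not tested, and it limits the values of both pools.

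Acute phase and complement genes were lower in the CR pool. Of 34 measured genes, 11 were at least 2-fold lower, and the median of -0.74 was reached by none of 10000 random lists. Serum amyloid genes Saa1 and Saa2 stood at -3.82 and -3.65, the fibrinogen chains Fgg and Fgb at -1.90 and -1.63, and the terminal complement gene C9 at -1.52. Hamp2, a hepcidin family gene, was higher at 1.51. Saa1 and Saa2 are near-identical and their separate values are uncertain. Without the complement genes that are also male-predominant, 8 of 31 genes were at least 2-fold lower and the median was -0.62.

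Inflammatory cytokine and NF-kB target genes had a median of -0.34 over 18 genes, at percentile 0.36, with Cxcl1 at -4.28, the early response gene Junb at -1.14 and the adhesion molecule Icam1 at -1.09 past 2-fold. The median was -0.20 with no intensity limit, and at the stricter limit it was -0.28 at percentile 9.29, inside the random range. Interferon response and antigen presentation genes had a median of -0.04 over 31 genes, with the antiviral gene Rsad2 at 1.12 (other probe set 0.03) and the GTPase gene Ifi47 at -1.16. Kupffer cell and neutrophil markers were lower beside these groups. Kupffer cell and macrophage markers, of which C1qa and Cd14 are also on the acute phase and complement list, had a median of -0.51 over 21 genes that no random list reached, with the lysozyme genes Lyz2 and Lyz1, close copies of each other, at -1.39 and -1.34. All 8 neutrophil markers lay below 0, with a median of -0.50 at percentile 0.19, and -0.30 with no intensity limit or -1.12 at the stricter one, and the calprotectin genes S100a8 and S100a9 stood at -2.29 and -1.75. Lymphocyte markers had a median of -0.28 over 10 genes, at percentile 4.39, with the immunoglobulin heavy chain gene Ighm at -1.23 and its 6 probe sets up to -0.20.

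Xenobiotic and intermediary metabolism lists held single genes of large difference around medians near 0. Of 39 phase I genes, 6 were at least 2-fold lower, among them the aldehyde oxidases Aox3 at -2.69 and Aox1 at -1.40 and the alcohol dehydrogenase Adh4 at -1.17. One, Cyp2c38, was higher at 1.03, and the list median was -0.08. Among 37 glutathione, phase II and NRF2 target genes, the glutathione transferase genes Gstt2 and Gstp1 stood at 1.82 and -1.04, 1 gene was at least 2-fold higher and 3 were lower, with a list median of -0.16 at percentile 3.55. When probe sets of a gene were averaged, that list lay at percentile 1.11, outside the random range, and at the stricter intensity limit at 2.33. Antioxidant enzymes had a median of -0.09 over 16 genes, with the glutaredoxin gene Glrx at 1.56 (other probe set 0.15). Of 40 amino acid catabolism and urea cycle genes, 2 were at least 2-fold lower, the cystathionine synthase Cbs at -1.02 and the tryptophan dioxygenase Tdo2 at -1.23, although another Tdo2 probe set stood at 0.00, and the list median was -0.13.

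Respiratory chain genes had a median of 0.00 over 42 genes, with the complex I subunit gene Ndufa5 at 1.02 (other probe set 0.66) as the single member past 2-fold. Tricarboxylic acid cycle genes had a median of 0.03 over 20 genes, with the dihydrolipoamide dehydrogenase gene Dld at -1.86 (43.4 in AL and 12.0 in CR). Cell cycle genes had a median of 0.06 over 25 genes, with the cyclin D1 gene Ccnd1 at -1.20, and the cyclin E2 gene Ccne2 lay below the measured range in AL and at 14.0 in CR. Of the lobular zone lists, 23 pericentral genes had a median of -0.16 and 21 periportal genes one of -0.01, with Cyp2f2 at -1.77 and the adhesion gene Cdh1 at -1.31 in the periportal list.

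Cholangiocyte markers had a median of 0.27 over 10 genes, at percentile 98.37, with no member past 2-fold, and after scaling -0.75 on all hybridisation controls and -0.10 on cre alone. They lay inside the random range without probe sets that can match several transcripts, and with no intensity limit and at the stricter limit, where the median was 0.12 in both. Hepatocyte markers had a median of -0.19 over 20 genes, with Fgb at -1.63, stellate cell, fibroblast and matrix markers -0.14 over 30, and endothelial markers -0.15 over 21. The endothelial list lay at percentile 0.73 without probe sets that can match several transcripts. Among 8 erythroid genes, with a median of -0.11, the heme synthesis enzyme gene Alas2 stood at -2.43 and the transferrin receptor Tfrc at -1.01. Adipocyte markers had a median of 0.09 over 7 genes, with Car3, a carbonic anhydrase also abundant in liver, at -1.70 on a probe set of 11409 in AL and its probe sets spread from -3.04 to 0.21. Pancreatic markers had a median of 0.14 over 7 genes, with the elastase gene Cela1 at -1.41, and skeletal and smooth muscle markers 0.29 over 3 genes.

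**Figure D2:**
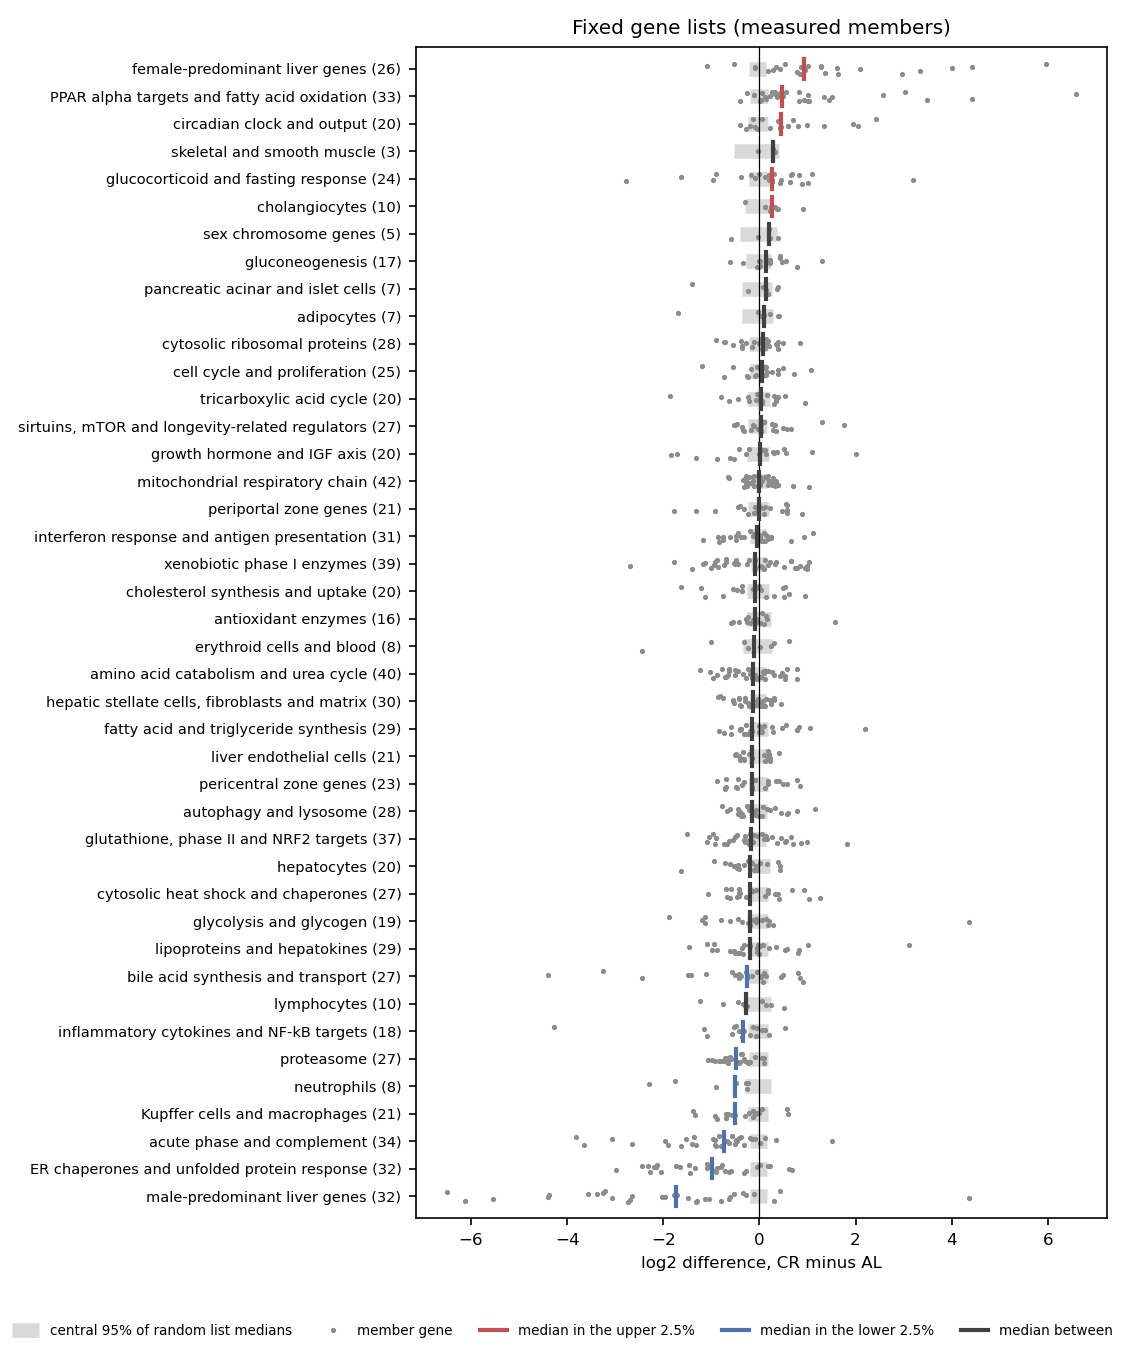
Log2 difference (CR minus AL) of the members of 42 fixed gene lists, with the number of measured members in parentheses; points are genes, vertical bars list medians, and grey bands the central 95% of medians of 10000 random lists matched on expression. In values as deposited, male-predominant genes (-1.74), ER chaperones (-0.99) and acute phase genes (-0.74) lie farthest below their bands and female-predominant genes (0.93) farthest above, although this last median is -0.09 after scaling on all hybridisation controls and 0.56 on cre alone.

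By these percentiles, 5 of the 42 lists lay in the upper 2.5% of random lists and 8 in the lower 2.5%. If the lists were random draws of genes, 1.05 would fall in each. Genes of a list can vary together and some lists share members. More lists can thus fall there without an effect of the diets. Female-predominant, PPAR alpha, clock, fasting and cholangiocyte genes made up the upper group. Male-predominant, ER chaperone, proteasome, acute phase, inflammatory, bile acid, Kupffer cell and neutrophil genes made up the lower group. The percentiles describe these 2 arrays and do not test the diets.

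**Figure D3:**
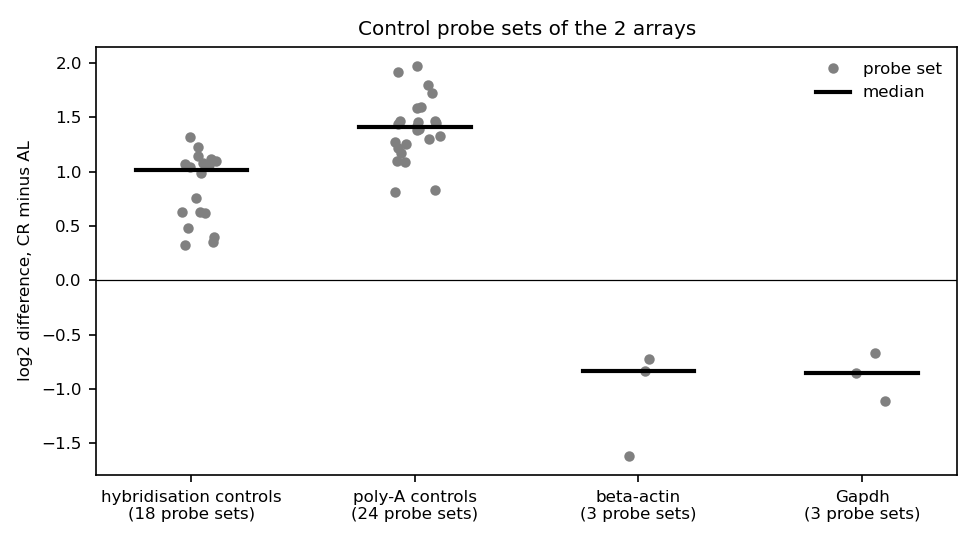
Log2 difference (CR minus AL) of control probe sets; points are probe sets and bars their medians. All 18 hybridisation control and all 24 poly-A control probe sets lie above 0, with medians of 1.02 and 1.41, and the 6 beta-actin and Gapdh probe sets lie between -1.61 and -0.67.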

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

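All tests in this part were chosen after the results were seen. Signals outside the comparison of genes came from the control spikes and from probe sets without a single gene name. All 18 hybridisation control probe sets were higher on the CR array, with a median difference of 1.02, and all 24 poly-A control probe sets were higher, with a median of 1.41. Of 3072 probe sets with no gene symbol in the measured range, 85 were at least 2-fold higher in CR and 31 lower, against 404 higher and 603 lower among 20316 probe sets with 1 symbol. Of 587 probe sets with several symbols, 12 were at least 2-fold higher and 22 lower. No control arrays were used here.

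The spikes, which are bacterial or phage RNAs in amounts not given in the sources used here, differed in size by transcript, with hybridisation medians of 1.13 for bioB, 1.05 for bioC, 0.63 for bioD and 0.37 for cre. In that order the medians fell as the intensity of the spikes rose, and the cause of this was not tested. Less labelled liver target on the CR array and more spike added to the CR sample both give higher hybridisation controls, so their median of 1.02, which prompted the question, does not decide between them. A lower mRNA share of the CR total RNA alone would raise the poly-A spikes, added before labelling, and not the hybridisation controls. The poly-A median exceeded the hybridisation median by 0.39, but the mass of target hybridised is not given, so this cannot be told apart from the other sources. The diets stay an open and untested source of a difference in RNA content.

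The opposite placing of sex-biased genes was weighed against 2 technical sources, female RNA and a difference in 1 mouse of the pool. Female RNA in the CR pool would lower the Y-linked Eif2s3y as much as the male-predominant genes, yet its difference was -0.031, above their median by 1.71, where genes of similar expression spread from -1.18 to 1.09. One scaling factor for the whole array moves all genes alike, so by construction it changes neither list's place among random lists. A loss in 1 of the 3 CR mice, with the others at the AL level, could lower a pool to no less than -0.58. The male-predominant median was -1.74, and its upper bootstrap bound over members, -1.04, lay below that. This bootstrap measures spread between genes of the list and not between mice, pools or arrays. An excess in 1 AL mouse can give any male-predominant median, here -1.74, and a gain in 1 CR mouse any female-predominant median, here 0.93, so for both lists a single mouse cannot be told apart from all, and an effect of the diet remains an untested hypothesis.

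Lower ER chaperones and acute phase genes were the third pattern. Fewer macrophages in the CR tissue would lower ER chaperones by no more than macrophage markers, yet the ER median minus the macrophage median was -0.48, with a bootstrap interval over members from -1.19 to -0.12 that left out 0. That interval also measures spread between genes only, so the spread between mice, pools or arrays stays unknown. Of the 21 macrophage genes, C1qa and Cd14 are also on the acute phase list. Those with the 5 highest AL intensities, which do not rank abundance, were Cd5l, Csf1r, Ctss, C1qb and Lyz1, at -0.08, -0.09, -0.30, 0.05 and -1.34. Stronger 3' bias of the CR RNA stays open, since the 3' to middle ratio was higher by 0.89 for beta-actin and 0.44 for Gapdh, the 3' to 5' ratio by 0.10 and 0.18, and probe set positions were not used here. One AL mouse with an acute phase response could give the Saa1 difference of -3.82, which a pool cannot tell apart from a difference in all mice, and an effect of the diet stays open.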

How the results depend on the processing

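The alternatives scaled on all hybridisation controls or on cre alone, limited to genes whose probe sets agree in sign, and run on lists without shared members were chosen after seeing the data. Against 227 higher and 353 lower genes, averaging all probe sets of a gene gave 110 and 230, a 1.5-fold threshold gave 855 and 1200, and scaling gave 33 and 6857 on all hybridisation controls and 96 and 1030 on cre alone. Averaging pulls each gene toward its dimmer probe sets, a lower threshold admits more genes by construction, and the spikes lower every difference by 1.02, or by 0.37 for cre. Scaling on all the spikes also turned the medians of all 5 lists placed high, to -0.086 for female-predominant genes, -0.54 for PPAR alpha targets, -0.57 for clock genes, -0.74 for fasting genes and -0.75 for cholangiocytes, and left their order among random lists as it was, since it moves all genes alike. On cre alone, a spike far brighter than most probe sets, the medians turned only for fasting genes, to -0.10, and cholangiocytes, to -0.10. Female-predominant genes kept 0.56, PPAR alpha targets 0.10 and clock genes 0.07. On bioD alone only the female-predominant median stayed above 0, at 0.30, and on bioB or bioC, the dimmest spikes, none did. The counts in the other settings ranged from 153 to 273 higher and from 306 to 353 lower. Removing the intensity limit changed neither count because no gene under it differed 2-fold. The share of 2-fold genes that were higher was 39.1%, 47.2% with each array centred on its median and 0.479% on all the spikes.

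Of the 13 lists placed outside the random range, 11 to 13 kept their place in each setting and none changed sides. Centring each array on its median moves all genes alike, so by construction all 13 kept their place there. The lists that lost their place in some setting were the bile acid, inflammatory and cholangiocyte lists. Of 139 named genes with at least a 2-fold difference, 29 were under 2-fold when probe sets were averaged, and 9 of 115 without probe sets that can match several transcripts. The cause was not tested. Without those probe sets the male-predominant median was -1.59 over 27 genes. The neutrophil median was -0.30 with no intensity limit and -1.12 at the stricter one. Of 50 named 2-fold genes with several measured probe sets, 28 had a probe set under 2-fold. No paired analysis was possible because each group had 1 sample. Signal near background limits genes of low intensity, with 15 higher and 30 lower genes below the limit in 1 pool. The strong 3' bias of the beta-actin and Gapdh controls on both arrays is a further limit.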

Other observations

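The values in this part were picked after the results were seen and are given without a test. Several of the 2-fold differences lay in genes with some of the brightest probe sets. In the tenth of measured genes with the highest mean intensity, 60 genes were at least 2-fold lower in CR and 39 higher. Gstp1, a pi-class glutathione transferase that male mouse liver holds in excess, stood at 13396 in AL and 6506 in CR, a difference of -1.04. Mt1, a metallothionein, stood at 6559 and 2110 (-1.64, other probe set -0.94), the fibrinogen chain Fgb at 6666 and 2155 (-1.63), and the steroid dehydrogenase Akr1c6 at 4223 and 1959 (-1.11). Plin2, the coat protein of lipid droplets, stood at 3766 and 6677 (0.83), and G0s2, an inhibitor of the lipase that empties them, at 451 and 2069 (2.20).

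In the tenth with the lowest mean intensity, 4 genes were at least 2-fold higher and 10 lower. Of the 30 genes with the largest differences, 5 were on none of the fixed lists. Among these, Adh6-ps1, an alcohol dehydrogenase pseudogene, stood at 132 in AL and 13.1 in CR (-3.33). The uncharacterised gene 1810053B23Rik stood at 8.37 in AL and 104 in CR (3.64). Rab30, Gpat3 and Lepr made up the rest, at 3.22, 2.61 and 2.57, with other Rab30 and Lepr probe sets at 1.88 and 0.37.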
